A study of Mus musculus with 12 samples.

How the data were processed

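Retinal pigment epithelium and choroid were collected from male C57BL/6 mice aged 2 and 24 months. Per the labels, total RNA was amplified by PCR with the SMART system, labelled with radioactive phosphorus and hybridised to ATLAS arrays, with 3 independent replicates per age and no external controls. Whether a replicate is 1 animal or a pool is not given in the sources used here. The p-values set the age difference against the spread between these samples, which may not be the spread between animals. The label of 1 sample states that old and young mice came from different suppliers. If so for every sample, age and supplier cannot be told apart. PCR amplification can change the ratio between transcripts, and a radioactive signal can spread from a bright spot to its neighbours. Neither was measured here.

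The deposited values are linear spot intensity on 1185 spots per array set, never below 0. From the values, each array is a whole number times 1 factor, between 0.192 and 1 on array I and between 0.542 and 1.46 on array II, with a tolerance of 0.002 whole units. The authors thus appear to have scaled each array by 1 factor. The rule for the factor, the imaging software and the background correction are not given in the sources used here. A deposited 0 can mean no transcript or a signal at or below background. Each array set was in a table of its own and was tested on its own, and 0 columns were left unused.

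Samples were grouped by the age in the labels, and replicates were numbered in accession order. The number in the sample titles links the 2 arrays of a sample but does not pair young with old. The array medians differed by more than 10%, so the 6 arrays of each set were quantile normalized. Values were transformed as log2(intensity + 2). The pseudocount of 2 is the 25th percentile of the deposited values above 0, and folds on that scale understate the change of dim spots. Folds in the text are ratios of mean deposited intensity. Spots above 0 on at least 3 of the 6 arrays were tested, 751 on array I and 568 on array II. The 24-month arrays were compared with the 2-month arrays in limma 3.58.1 under R 4.3.3 (lmFit and eBayes without trend), with Benjamini-Hochberg adjustment over the tested spots of the set and a threshold of 0.05. An exact permutation test of 3 against 3 cannot go below a two-sided p of 0.1, so none was used for single spots. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

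The design, the rule for naming spots and all alternatives but 3 were fixed before the data were examined. The rule took the spots past the threshold by size of the log2 difference or, with fewer than 10 such spots, the 10 spots with the smallest p, given as values. As fixed, the rule allowed more spots per direction and did not name probes without a gene. No gene names are paired with the spots in the sources used here. As a departure from the rule, spots are printed by ID, at most 2 per direction and set. They are the first of each direction in the order of the rule. Other spots were chosen after their values were seen, as stated where they appear. The planned tests of gene lists, cell type markers and housekeeping genes need gene names and were not run. The planned rule did not say whether the pseudocount came from deposited or normalized values. The deposited values were used, and the other reading was run as an alternative added after seeing the data, as were the restriction to spots above 0 on all 6 arrays and median scaling with array weights. Because array medians are often 0, median scaling used the median over spots above 0 on all 6 arrays. Other alternatives changed the pseudocount, the filter on dim spots, the moderation, the weights and the arrays left out.

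The procedure was tested on simulated intensities in which 200 spots were changed by known folds. On array I, 14.9%, 69.4%, 88% and 98% of spots changed 2-, 4-, 8- and 16-fold were recovered, with 9 unchanged spots called among 860 tested. On array II, 62.5% of the 2-fold and 95.9% of the 4-, 8- and 16-fold changes were recovered, with 11 unchanged spots called among 566 tested. With no change simulated, 0 spots were called on either set. The simulation of array I tested 860 spots against 751 in the data. On both sets, many changed spots loosen the Benjamini-Hochberg cut-off, whereas the data gave 0 calls on array I and 11 on array II. These shares are therefore not the recovery on the real arrays and can be too high for both sets. In the data, spot M398 of array I differed 15.0-fold in mean intensity and had a limma adjusted p of 0.086. A count of 0 on array I therefore does not exclude large differences.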

Results

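Gene expression in the retinal pigment epithelium and choroid was compared between young and old mice. The retinal pigment epithelium is the pigmented cell layer that supports the photoreceptors, and the choroid is the vascular layer beneath it. Both were collected together from male C57BL/6 mice aged 2 or 24 months, and the labels state that other parts of the eye were excluded. Amplified, radioactively labelled cDNA was hybridised to ATLAS arrays, which carry gene fragments spotted on a membrane. Each sample was run on 2 array sets, called array I and array II, so the 12 arrays hold 3 replicates per age on each set. Each set has 1185 spots, and 9 spot IDs are present on both. The sources used here do not pair spots with gene names, so spots are given by ID and no gene or pathway is named.

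Array I carried a total intensity of 32717 to 36965 per array, and array II 7575 to 11963. Spot MA279 alone held 17.6% to 40.7% of the total on array I, whereas the brightest spot of array II, MB780, held 3.59% to 9.74%. Both spots were singled out for brightness after their values were seen. On array I, 480 spots were above 0 on all 6 arrays and 57 were listed at 0 on all 6. The corresponding numbers on array II were 338 and 419. Between 583 and 1096 spots were above 0 per array on array I, with the highest number on 2-month replicate 1, and between 450 and 614 on array II. The number of arrays, 3 per age, limits the precision of every comparison.

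Across the tested spots of array I, the 24-month arrays correlated with each other at Pearson r of 0.942 to 0.961. The 2-month replicates 2 and 3 correlated at 0.919, and 2-month replicate 1 had a mean r of 0.471 with the other 5 arrays. On array II, r was 0.957 to 0.966 within the 24-month arrays and 0.843 to 0.885 within the 2-month arrays. These correlations are across spots, which are not independent replicates.

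**Figure D1:**
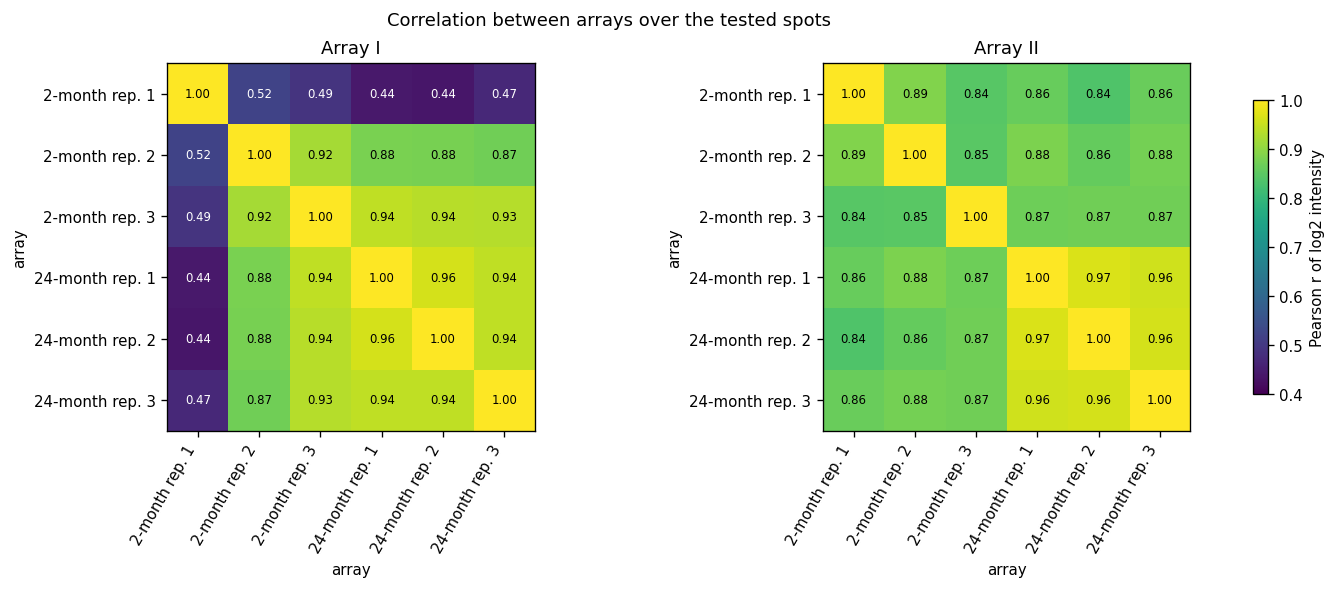
Pearson r of log2 intensity between each pair of arrays over the tested spots of array I (left) and array II (right), with 1 row and 1 column per array. The 2-month replicate 1 of array I has a mean r of 0.471 with the other 5 arrays, and the 24-month arrays correlate at 0.957 to 0.966 on array II.

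The first comparison asked which transcripts of array II differed between 2 and 24 months. Spot MB742 rose from an intensity of 31.0 ± 5.16 (SD, n = 3) at 2 months to 533 ± 97.1 (SD, n = 3) at 24 months, a 17.2-fold difference of means. Spot MA964 rose from 34.1 ± 6.12 (SD, n = 3) to 477 ± 120 (SD, n = 3), a 14.0-fold difference. For both spots every 24-month array lay above every 2-month array. On the log2(intensity + 2) scale the difference was 3.97 for MB742, with a limma standard error of 0.20 and a Benjamini-Hochberg adjusted p of 5.1e-04. For MA964 it was 3.36, with a standard error of 0.20 and a limma adjusted p of 8.9e-04. After quantile normalization MB742 had the same value on all 3 of the 24-month arrays, which lowers its measured spread.

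**Figure D2:**
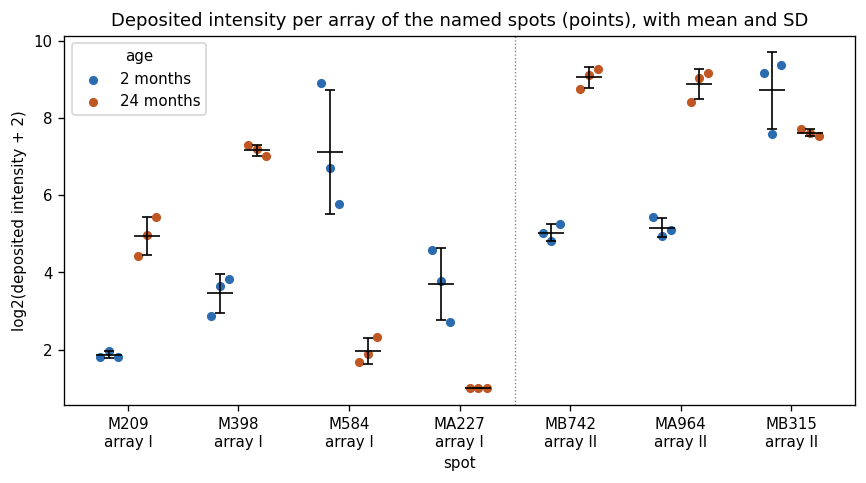
Deposited intensity of the 7 spots named by rule on each array, as log2(intensity + 2), with 2 months in blue and 24 months in orange. Points are single arrays, long horizontal bars the mean and whiskers the SD of 3 arrays. MB742 and MA964 of array II lie higher on every 24-month array, whereas 1 of the 2-month values of MB315 lies within its 24-month range.

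Of the 568 spots tested on array II, 11 passed an adjusted p of 0.05 in limma, 10 higher and 1 lower at 24 months. Without 2-month replicate 3 the split was 19 higher and 10 lower. At an unadjusted p under 0.05 there were 78 spots, 44 higher and 34 lower, where 28.4 are the number given by chance. This count was 44, 40 and 43 without 24-month replicates 1, 2 and 3, and 121, 97 and 125 without 2-month replicates 1, 2 and 3. The deposited intensities of the ages, before normalization, did not overlap for 90 tested spots, or 15.8%. Chance gives 10% on average over all splits of the arrays. The spots share the same arrays and the share was not computed for other splits, so this excess was not tested. Besides MB742 and MA964, 5 of the higher spots were dim, with 2-month means of 2.52 to 4.37 and 24-month means of 18.6 to 32.9. No fold is given for them, since their 2-month values were 2 to 8 whole units of the deposited scale and the smallest value above 0 was 2. Another rose 4.26-fold. The remaining 2 higher spots were listed at 0 on every 2-month array and were 3 whole units on every 24-month array, at most 2.44. After quantile normalization they were tied within each age, so their calls rest on ties at the lower end of the scale, and 9 of the 11 spots are free of this. The count changed with single arrays. It was 4 without 24-month replicate 1 or without 24-month replicate 3, 7 without 24-month replicate 2, 27 without 2-month replicate 1 and 29 without 2-month replicate 3.

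The single spot of array II that passed the threshold in the other direction was MB315. Its intensity was 475 ± 251 (SD, n = 3) at 2 months and 195 ± 13.0 (SD, n = 3) at 24 months, and its log2 difference was -1.41, with a standard error of 0.18 and a limma adjusted p of 0.016. As deposited, the 2-month values were 574, 189 and 661, and the second lay within the 24-month range of 183 to 209. Quantile normalization made the 2-month values 538, 425 and 538, against 175 to 197 at 24 months. It thus moved the second value out of the 24-month range and lowered the measured spread at 2 months. This call was lost with median scaling, where the limma adjusted p was 0.37, with the values as deposited, where it was 0.46, when both array sets were adjusted in 1 fit, where it was 0.077, and without any 1 of the 24-month arrays, where it was 0.10 to 0.16. The log2 difference was -0.93 with median scaling, -1.09 as deposited and -0.81 with median scaling and array weights, where the adjusted p was 0.33. It was -1.41 in the joint fit and -1.47, -1.41 and -1.35 without 24-month replicates 1, 2 and 3.

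**Figure D3:**
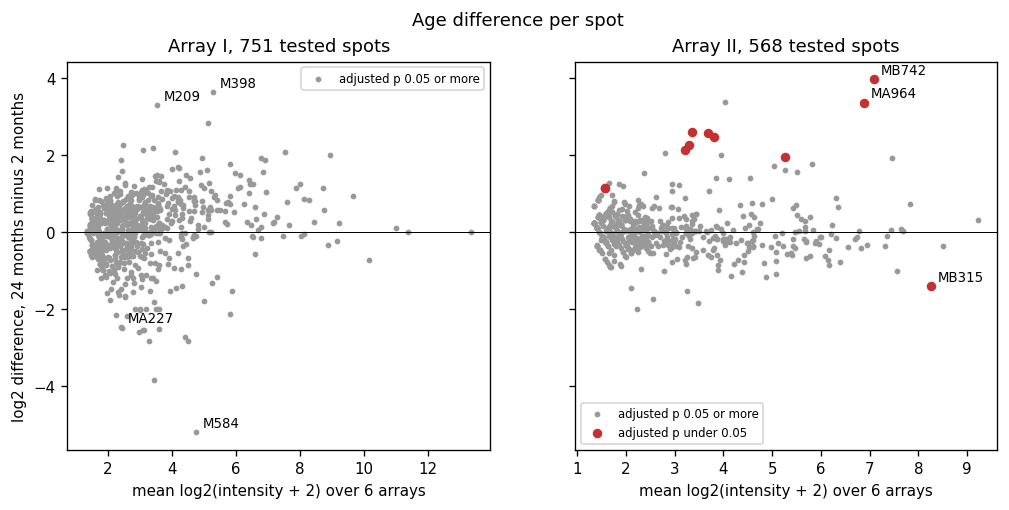
Log2 difference between 24 and 2 months against the mean log2(intensity + 2) for the 751 tested spots of array I (left) and the 568 of array II (right). Each point is a spot, and red marks a limma adjusted p under 0.05, which 0 spots of array I and 11 of array II reached.

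The second comparison asked the same of array I. Of its 751 tested spots, 0 passed an adjusted p of 0.05 in limma, and 4 had an adjusted p under 0.1, 2 higher and 2 lower at 24 months. At an unadjusted p under 0.05 there were 52 spots, 26 in each direction, where chance gives 37.6. This count changed with single arrays. It was 21, 20 and 31 without 24-month replicates 1, 2 and 3, below the 34.9, 36.8 and 36.6 given by chance. Without 2-month replicates 1, 2 and 3 it was 78, 47 and 123. The deposited intensities of the ages did not overlap for 139 tested spots, or 18.5%. Chance gives 10% on average over all splits of the arrays, and here too the excess was not tested against other splits. The median log2 difference over all tested spots was 0.19 with quantile normalization, -0.12 with the values as deposited and about 0 (-0.0043) with median scaling. It was 0.020 without 2-month replicate 1 and 0.43 without 2-month replicate 3, so differences of array I are also given relative to the median.

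The spots with the smallest p on array I are given as values, not as changes. Spot M584 had an intensity of 474, 103 and 52.2 on the 2-month arrays and of 1.19, 1.72 and 3 on the 24-month arrays. Its log2 difference was -5.19 (-5.38 relative to the median), with a standard error of 0.75 and a limma adjusted p of 0.053. Spot M209 measured 1.67 ± 0.232 (SD, n = 3) at 2 months and 30.0 ± 10.7 (SD, n = 3) at 24 months. Its log2 difference was 3.29 (3.10 relative to the median), with the same limma adjusted p of 0.053. Its 2-month values lay near the smallest value above 0, and the log2 difference ran from 2.10 with 4 times the pseudocount to 4.34 with the pseudocount taken from normalized values. Spot M398 measured 9.44 ± 3.61 (SD, n = 3) and 142 ± 13.7 (SD, n = 3), with a log2 difference of 3.64 (3.44 relative to the median) and a limma adjusted p of 0.086. Spot MA227 had intensities of 22.1, 11.6 and 4.61 at 2 months and was listed at 0 on every 24-month array, with a limma adjusted p of 0.086. Among the 10 spots with the smallest p, 6 were higher and 4 lower at 24 months, with adjusted p from 0.053 to 0.27.

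Array I of 2-month replicate 1 stood apart from the other arrays, and the count changed without it. In limma with the remaining 5 arrays, 2 spots passed the threshold. M398 was 12.3-fold higher at 24 months, with a log2 difference of 3.24, a standard error of 0.17 and an adjusted p of 0.0037. M584 was lower at 24 months, with a log2 difference of -4.60, a standard error of 0.47 and an adjusted p of 0.048. Its 24-month values lay at or next to the smallest value above 0, so no fold is given for it. With any 1 other array left out instead, neither spot passed. The limma adjusted p was then 0.16 to 0.50 for M398 and 0.097 to 0.33 for M584.

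The 9 spots present on both sets, M901 to M909, allowed the age difference to be compared between sets in the same samples. Of these, 0 passed the threshold on array I and 0 on array II, and 6 had the same direction on both. A limma test of the difference between the sets gave a lowest adjusted p of 0.85 over the 9 spots. This test used 1 pooled standard error of 1.35 on the log2 scale for every spot, which includes the arrays that stood apart, so it could detect only large differences. Spot M904 was bright on array I, with an intensity of 2139 ± 870 (SD, n = 3) at 2 months and 2270 ± 471 (SD, n = 3) at 24 months. On array II it measured 618, 177 and 1.08 on the 2-month arrays and 357 ± 62.6 (SD, n = 3) at 24 months. M904 was singled out after its values were seen.

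**Figure D4:**
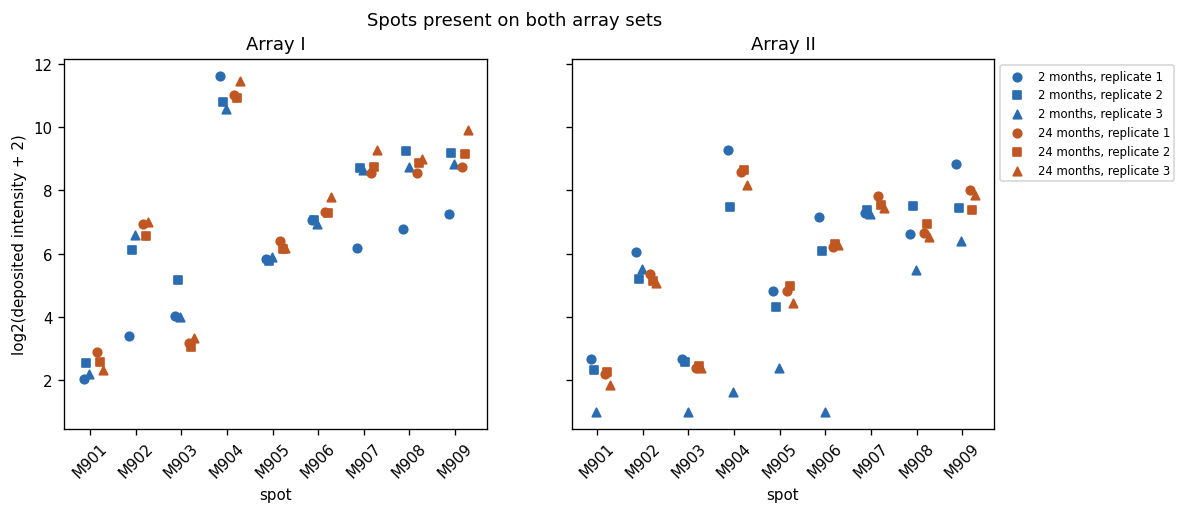
Deposited intensity, as log2(intensity + 2), of the 9 spots present on both array I (left) and array II (right). Colour gives the age and the symbol the replicate. On array II, M901, M903, M904, M905 and M906 of 2-month replicate 3 lie under 25% of the lowest of the other 5 arrays.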

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

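All tests of explanations in this part were chosen, and some revised, after the results they measure had been seen. For array I of 2-month replicate 1, the comparison of bright spots is the third version. The first kept this array in its own reference, and the second had a looser bound.

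Spots left out of the age test of array I reached an intensity of 201 on 2-month replicate 1, against at most 19.0 on any other array of the set. Of the 306 spots listed at 0 on the other 5 arrays, 249 were above 0 on this one, with a median of 2.69 and 51 over 10.

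This array also had a mean r of 0.471 with the others. A uniform raised background would place those spots in a narrow band, and 13.7% of them exceeded 5 times their median, which argues against it. An RNA sample that differs as strongly on both sets is argued against by array II. There the same sample had a mean r of 0.857, 0.0017 below the next lowest array, against a gap of 0.34 on array I. It was still the lowest on array II, and the next lowest, 2-month replicate 3, is itself in doubt. The 24-month arrays had 0.898 to 0.906, so a smaller difference on both sets stays open. Extra signal mainly on dim spots would leave the 100 brightest spots with an SD of the log2 ratio no higher than on the other arrays. That SD was 1.23 here and 0.51 to 0.89 on the others. On array I, M901, M902, M907, M908 and M909 lay below every other array, M904 above, and M903, M905 and M906 within their range. These values argue against extra dim signal as the whole cause, but the SD stayed short of the bound set for ruling it out. Another RNA on array I of 2-month replicate 1, through a wrong label or a mixed sample, stays open. Over the 9 spots on both sets, deviations of this sample correlated at Pearson r 0.63 (exact permutation p = 0.071) and Spearman rho 0.55 (exact permutation p = 0.13). The same Pearson r ran from -0.65 to 0.88 over the other samples, so it cannot tell a matching RNA from another. No biological explanation was tested, because the design gives this replicate no factor of its own.

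On array II of 2-month replicate 3, M901, M903, M904, M905 and M906 lay under 25% of the lowest other array, and M904 measured 1.08 against 177 to 618. M901 and M903 were dim, with lowest other values of 1.63 and 3.25. Their 0 on this array may reflect only the lower end of the scale. RNA lacking the transcripts of the 5 spots would leave them low on array I, where the lowest ratio to the lowest other array was 0.87. This argues against missing transcripts. On array I, M904 and M906 were still below every other array, at 0.87 and 0.93 of the lowest. Over the 9 spots on both sets, the deviations of this sample correlated at Pearson r 0.88 between sets, the highest of all samples. A smaller shift of this RNA on both sets thus stays open. A local fault of the membrane of array II or its readout is an untested candidate explanation. Of 107 spots at 10 or more on the other 5 arrays, 4 were under 25% of the lowest on this array, against 0 or 1 on each of the others, but 3 of these 4 are M904, M905 and M906, which prompted the count, so it adds little.

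The 24-month arrays were more alike than the 2-month arrays, with a mean r of 0.948 against 0.643 on array I and 0.962 against 0.858 on array II. On array II, leaving out 2-month replicate 3 leaves a 2-month pair at 0.885 and pairs between ages up to 0.881, against 0.957 or more within the 24-month arrays, which argues against that array as the whole cause. On array I, leaving out 2-month replicate 1 leaves a pair at 0.919 against 0.942 or more, but 2-month replicate 3 reached 0.944 with a 24-month array, so there the doubtful array stays open as the cause. Among 20 groups of 3 arrays, the 24-month arrays had the highest mean r on both sets, followed by 0.905 on array II and 0.947 on array I, and 20 groups cannot give a share under 0.05. Age, supplier and the handling of each age group were not tested apart and stay open.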

How the results depend on the processing

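The alternatives with the normalized pseudocount, the spots above 0 on all 6 arrays, and median scaling with array weights were chosen after seeing the data. The others were planned. The count of spots past the threshold on array I, 0 with quantile normalization, was 3 with median scaling, 2 with the values as deposited, 3 with robust moderation, 10 with array weights, 2 over spots above 0 on all 6 arrays and 10 with median scaling and array weights. Leaving out 1 array gave 0 to 2, with 2 without 2-month replicate 1, whose array weight was 0.078. On array II the count of 11 became 15 with median scaling and 13 with the values as deposited, all higher at 24 months. Each of these shared 8 spots with the 11. Without the filter on dim spots the count was 12, sharing 7. It was 25 (19 higher, 6 lower) with 4 times the pseudocount, 17 with robust moderation and 4 with both sets in 1 fit. Over spots above 0 on all 6 arrays it was 23, and with median scaling and array weights 19. Leaving out 1 array gave 4 to 29. It was 4 without 24-month replicate 1 or 3, 7 without 24-month replicate 2, 27 without 2-month replicate 1 and 29 (19 higher, 10 lower) without 2-month replicate 3. The cause of these shifts was not tested. MB742 and MA964 passed under all 19 alternatives. MB315 passed under 12 and did not under 7, with adjusted p from 0.0038 to 0.46. On array I, M209, M398 and M584 each passed under 6 of 19 alternatives and MA227 under 2 of 15. In 10 splits of the 6 arrays, the real split of array II gave 11 spots and the highest other 0. On array I the real count was 0, so all 10 splits had to give as many, and they say nothing about age there. The highest other count was 0. With 10 splits, no share under 0.05 can be reached, and on array II 1 split, the real one, gave as many. No paired analysis was possible because young and old samples share no number in the labels. Gene list alternatives were not run, quantile normalization was already in use, and the filter to brighter spots left 564 of the 568 spots of array II, so it tests little there. Dim spots near 0 limit what array signal over background can show.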

Other observations

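Spots listed at 0 in a single age were counted after the data had been seen, and no difference between the sets was tested. On array II, 13 spots were above 0 on every 24-month array and at 0 on every 2-month array, with a highest intensity of 3.49, and 0 spots showed the opposite. The smallest value above 0 was 2 whole units on each array of this set. A unit was 1.46, 1 and 0.542 on 2-month replicates 1, 2 and 3 and 0.65 to 0.813 on the 24-month arrays. These unequal lower limits affect such counts. Without 2-month replicate 1, 35 spots of array II were seen only at 24 months and 1 only at 2 months. On array I, 17 spots were above 0 on every 2-month array and at 0 on every 24-month array, and 2 of them exceeded an intensity of 3 on both 2-month replicates 2 and 3. The opposite count, 0 on array I, was nearly fixed by 2-month replicate 1, on which only 32 of the spots above 0 on some other array were at 0. Without that replicate the counts on array I were 17 spots seen only at 2 months and 9 seen only at 24 months.

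Array II spots whose IDs start with MA, MB and MC held 4, 6 and 1 of the spots past the threshold, among 224, 313 and 22 tested. What the prefixes stand for is not given in the sources used here.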
